A study of Mus musculus with 16 samples.

How the data were processed

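The study measured gene expression in the hippocampus of C57BL/6 mice aged 8 to 10 weeks with Affymetrix arrays hybridised to biotin-labelled cDNA from total RNA. There were 16 arrays in 4 groups of 4, given by genotype and treatment. Control mice carried a glial cre and no floxed Dio2 per the labels, and Astro-D2KO mice carried floxed Dio2 with the glial cre. All mice received lithium chloride at 10 mEq/kg and, 18 h later, either saline or pilocarpine at 65 mg/kg, which induces status epilepticus (SE), a prolonged seizure. The interval between pilocarpine and tissue collection, the sex of the mice and any hybridisation batch are not given in the sources used here.

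The deposited values were made with RMA per the submitters' notes, which corrects the background, normalises the arrays by quantiles and summarises each probe set. The deposited values were read as log2 units. The log base is not written in the table; it was inferred from values between 1.70 and 13.79 and array medians between 5.77 and 5.82. The table held 41345 probe sets in each of the 16 arrays. Arrays have no read depth, so the number of arrays per group limits the precision.

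Probe sets were paired with genes through the annotation table that goes with the series. Of the probe sets, 23521 had exactly 1 gene symbol, 1814 had several and 16010 had none. The Entrez identifiers of 23328 of the single-symbol probe sets were found in a RefSeq table, which changed 0 symbols. For the 1082 genes with more than 1 probe set, the probe set with the highest mean over all 16 arrays stood for the gene, which left 22180 genes. No gene was filtered on its level. Genome positions were not used.

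Limma 3.58.1 in R 4.3.3 fitted 1 mean per group to the log2 values, with a spread per gene shared by the 4 groups and moderated by empirical Bayes with default settings. There were 7 contrasts: SE against saline in control mice, in Astro-D2KO mice and averaged over genotypes, Astro-D2KO against control under saline, after SE and averaged over treatments, and the interaction, which is the SE response of Astro-D2KO mice minus that of control mice. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 22180 genes within each contrast, with a threshold of 0.05. Errors of log2 changes are the standard errors of this fit, and group values are means with standard deviations over 4 arrays. Dio2, the targeted gene, was also tested by an exact permutation test of 4 arrays against 4, which has 70 arrangements and a smallest two-sided p of 0.0286. The fit was tested on 1 simulated comparison, that of Astro-D2KO with control mice after SE: with 200 genes altered, limma recovered 49 of 67 genes altered by 0.5 on the log2 scale, 64 of 67 altered by 1 and 66 of 66 altered by 2, with 12 false calls beside 179 true calls. The simulated noise was normal and independent between genes, and no simulated array stood apart from its group. The real arrays can differ in these respects, so the shares do not bound the changes that a real comparison could miss.

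Before the data were examined, 38 gene lists were fixed from textbook knowledge. They covered thyroid hormone metabolism, transport and receptors; genes raised by T3 and genes lowered by T3 in brain; immediate early genes; later activity-regulated genes and neuropeptides; cytokines, chemokines and NF-kB targets; pan-reactive, A1 and A2 astrocyte genes; NRF2 and antioxidant genes; heat shock proteins and chaperones; the integrated stress response and unfolded protein response; glucocorticoid-responsive genes; glutamate receptors; GABA signalling genes; voltage-gated channels; cholesterol synthesis; the mitochondrial respiratory chain; glycolysis and glucose transport; and the circadian clock. Marker lists covered astrocytes, microglia, oligodendrocytes, oligodendrocyte precursors, endothelium, pericytes and smooth muscle, choroid plexus, leptomeningeal fibroblasts, blood cells, neurons in general, dentate granule cells, CA1 pyramidal cells, CA2 and CA3 pyramidal cells, interneurons, thalamus and habenula, striatum, neocortex and sex-linked genes. The lists named 660 distinct symbols, of which 588 were measured. Each list was tested with camera from limma, which compares the members of a list with all other genes, at a preset correlation between genes of 0.01, adjusted over the 38 lists within a contrast. Camera with an estimated correlation and fry were run as alternatives. Fry tests whether the genes of a list move, on balance, one way and does not compare the list with other genes; its mixed form tests for change in either direction. Members of a list that passed were counted with adjustment over all genes and with adjustment over the list alone.

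The genes named in each contrast were chosen by a rule fixed before the data were examined. It took the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose arrays did not overlap between the groups. Where fewer than 5 genes passed, it took the 5 with the smallest raw p. It added Dio2, Dio3, Thra, Thrb, Hr and Klf9, and from each list up to 2 members with the largest rise and 2 with the largest fall among those that passed, or the member with the smallest raw p. Predicted genes, Riken clones, microRNAs, small nucleolar RNAs and olfactory receptors were counted and not named among the largest changes or the smallest raw p.

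Alternatives fixed in advance were an intensity trend with a robust prior, array weights, removal of the third of genes with the lowest mean, centring each array on its median, a repeated quantile normalisation, the replicate number as a block, the mean over a gene's probe sets, every probe set tested, an adjusted p threshold of 0.01, an added 1.5-fold minimum, a fit of only the 2 groups compared, the other probe set of Dio2, and leaving out each array in turn. Chosen after seeing the data were leaving out the arrays labelled control SE replicate 4 and Astro-D2KO SE replicate 1 together, each of the 16 pairs made of a control SE array and an Astro-D2KO SE array, and fits with the mean of the choroid plexus list or the first principal component of the residuals as a covariate.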

Results

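Hippocampal expression was measured in 16 mice, 4 in each of the 4 groups formed by genotype (control or Astro-D2KO) and treatment (saline or SE). Astro-D2KO mice were made to lack, in astrocytes, the type 2 deiodinase encoded by Dio2, the enzyme that turns thyroxine (T4) into the active hormone T3. The levels of the 22180 genes were closely related between arrays, with Pearson correlations across probe sets from 0.969 to 0.990. The first principal component held 47.4% of the variance and the second 10.8%. No array was identical to another.

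Dio2, the gene targeted in Astro-D2KO mice, stood at 8.14 ± 0.19 (log2, SD, n = 4) in control mice under saline and at 6.78 ± 0.23 (SD, n = 4) in Astro-D2KO mice under saline, 2.57-fold lower, with no overlap between the arrays. The two-sided exact permutation p was 0.0286, the smallest that 4 arrays against 4 can give. After SE the level was 8.96 ± 0.67 in control mice and 7.56 ± 0.91 in Astro-D2KO mice, 2.66-fold lower (n = 4 each, exact permutation p = 0.0571), and the groups overlapped. The control SE arrays, replicates 1 to 4, stood at 9.51, 9.11, 9.24 and 7.99. The Astro-D2KO SE arrays, replicates 1 to 4, stood at 8.91, 7.03, 7.17 and 7.12. Thus the array labelled Astro-D2KO SE replicate 1 had a Dio2 level far above the other Astro-D2KO SE arrays, against its label. It lay within the range of the control SE arrays only through the array labelled control SE replicate 4, and below the other control SE arrays. The array labelled control SE replicate 4 lay below the other control SE arrays and within the range of control mice under saline, 7.87 to 8.28. It also lay above Astro-D2KO SE replicates 2 to 4. SE went with a Dio2 difference of 0.82 ± 0.35 in control mice (1.77-fold, exact permutation p = 0.114) and of 0.77 ± 0.35 in Astro-D2KO mice (1.71-fold, exact permutation p = 0.0571), neither of which passed. A second, dimmer Dio2 probe set with a mean of 5.07 gave differences between genotypes of -0.09 under saline and -0.12 after SE, with exact permutation p of 0.686 and 0.657, and so gave no check of the labels. Whether either probe set lies in the deleted part of Dio2 is not given in the sources used here; a probe set outside that part would check nothing.

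**Figure D1:**
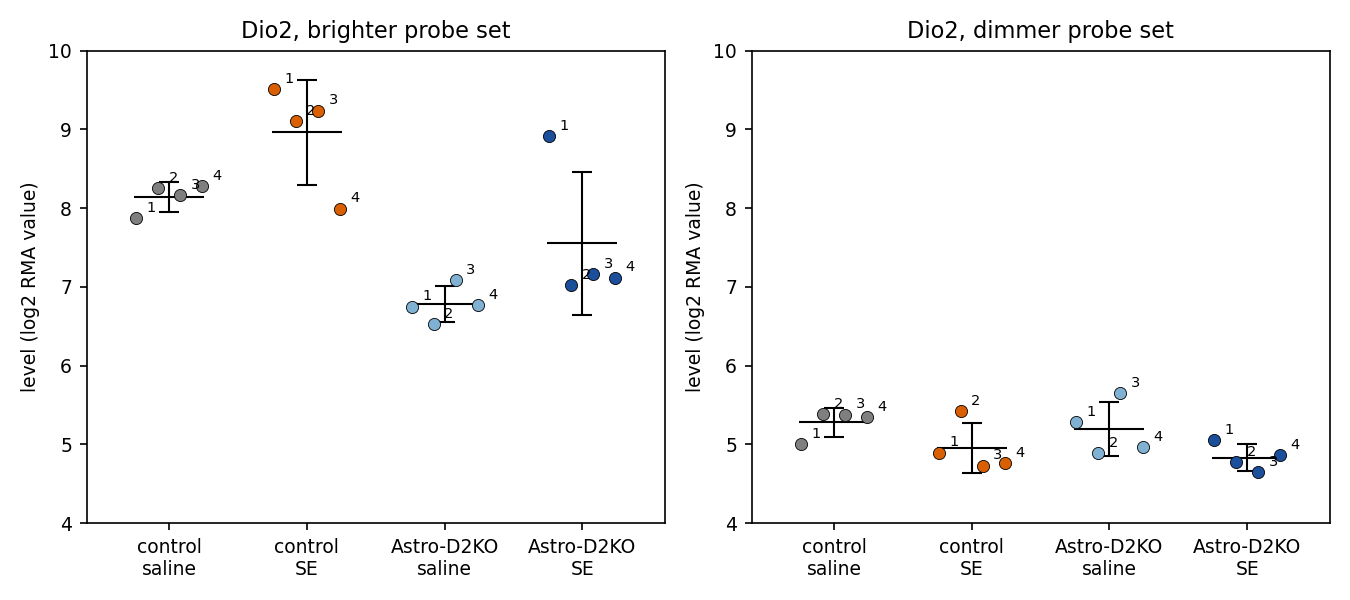
Dio2 level (log2 RMA value, vertical axis) in each array of the 4 groups, for the brighter and the dimmer probe set. Points are arrays numbered by replicate, and lines are the group mean and SD. In the brighter probe set the 4 Astro-D2KO saline arrays lie between 6.52 and 7.09 and the 4 control saline arrays between 7.87 and 8.28, while the array labelled Astro-D2KO SE replicate 1 lies at 8.91.

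The first comparison asked how SE alters the hippocampal transcriptome of control mice. In both genotypes all SE mice received pilocarpine and no saline mouse did. Effects of the drug and of the seizures thus cannot be told apart in any SE comparison. The largest rises were of Npas4, a neuronal transcription factor switched on by activity, and of Hspa1a and Hspa1b, the inducible Hsp70 chaperones. Npas4 rose by 4.97 ± 0.39 on the log2 scale (31.4-fold), from 5.79 ± 0.20 to 10.76 ± 1.22 (SD, n = 4), and Hspa1a rose by 4.95 ± 0.32. Without the array labelled control SE replicate 4, where Npas4 stood at 8.96 against 11.13 to 11.57 in the other control SE arrays, its rise was 5.57. Fosb (4.58 ± 0.17) and Fos (3.87 ± 0.33), components of the AP-1 transcription factor, rose with Inhba (3.99 ± 0.30), a subunit of activin, and Ccl3 (3.95 ± 0.41), a chemokine. Pcsk1, a protease that processes prohormones, rose by 3.36 ± 0.094 with the smallest adjusted p, 2.56e-13. The largest fall was of Slco1a4, an organic anion transporter of brain endothelium that also carries thyroid hormone, which dropped by 2.16 ± 0.21 to a level 4.47-fold lower than under saline.

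In control mice, limma called 4907 of the 22180 genes, of which 1867 rose and 3040 fell. The balance depended on the scaling, with 2148 rises and 2510 falls when each array was centred on its median and 1998 and 2724 with quantile normalisation repeated. With a 1.5-fold minimum 818 rose and 442 fell. At least a 2-fold change was seen in 323 of those that rose and 27 of those that fell. The rest of the 10 largest rises were of Hspa1b (4.94), Atf3 (3.37), a stress-induced transcription factor, and Egr1 (3.29), an activity-induced one. The other large falls were of Dsp (-1.75) and Lct (-1.19), both markers of dentate granule cells, of the zinc finger genes Zkscan16 (-1.46), Zfp975 (-1.25) and Zfp759 (-1.16), and of Fam163b (-1.38), Ppil6 (-1.13), Narf (-1.13) and Wdr19 (-1.12), the last encoding a protein of transport within cilia. The count was made with the array labelled control SE replicate 4 in its labelled group.

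Neuronal activity genes rose as groups in control mice. Of the 35 measured immediate early genes, 33 rose and 0 fell (34 and 0 adjusted over the list alone), with a median of 2.03 and a camera adjusted p of 3.56e-46. Of the 33 later activity-regulated genes and neuropeptides, 29 rose and 0 fell (29 and 0 adjusted over the list alone), with a median of 1.52 and a camera adjusted p of 4.82e-32. Of the 15 heat shock proteins and chaperones, 12 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 1.08 and a camera adjusted p of 8.35e-15. Those were the 3 list calls that held with an estimated correlation in control mice, with adjusted p of 0.00383, 0.00383 and 0.0148. All other list calls in this comparison, 10 of 13, were lost with it.

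Inflammatory and stress genes also rose. Of the 32 cytokines, chemokines and NF-kB targets, 22 rose and 0 fell (23 and 0 adjusted over the list alone), among them Ccl3 and Osmr (1.58), the oncostatin M receptor. The camera adjusted p was 8.41e-14, and the adjusted p = 0.0714 with an estimated correlation. Of the 12 A2 reactive astrocyte genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone), including Ptgs2 (3.07), the inducible cyclooxygenase, and Cd14 (2.01), a co-receptor for endotoxin; the camera adjusted p was 5.47e-07, against an adjusted p = 0.201 with an estimated correlation. The mean of the A2 list was 1.12 in the array labelled control SE replicate 4 and between 0.22 and 0.30 in the other control SE arrays. Of the 13 pan-reactive astrocyte genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone), Osmr and the small heat shock protein gene Hspb1 (1.53), with a camera adjusted p of 0.00289 and an adjusted p = 0.432 with an estimated correlation. Of the 8 A1 reactive astrocyte genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.260). Of the 19 genes of the integrated stress response and unfolded protein response, 10 rose and 0 fell (11 and 0 adjusted over the list alone), including Atf3 and Hspa5 (1.13), the chaperone of the endoplasmic reticulum. That list had a camera adjusted p of 6.69e-08 and an adjusted p = 0.143 with an estimated correlation. Several of the genes named here are on other called lists too, and each list was tested with its shared members. Hspb1 and Hspa5 are on that of heat shock proteins, and Osmr is on that of cytokines. Ptgs2 is on that of later activity-regulated genes, and Atf3 is on that of immediate early genes.

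Camera also called the glucocorticoid, cholesterol synthesis and respiratory chain lists in control mice, none of them with an estimated correlation, and did not call glycolysis and glucose transport. Of the 20 glucocorticoid-responsive genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone), with Dusp1 (2.56), a phosphatase of MAP kinases, and Errfi1 (2.10), an inhibitor of EGF receptors, the largest. Dusp1 is also on the list of immediate early genes. The camera adjusted p was 6.33e-07, and the adjusted p = 0.108 with an estimated correlation. Of the 17 cholesterol synthesis genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone), among them Pmvk (1.42) and Msmo1 (1.15), enzymes of the pathway; the camera adjusted p was 1.07e-07, against an adjusted p = 0.121 with an estimated correlation. Of the 32 genes of the mitochondrial respiratory chain, 0 rose and 13 fell (0 and 17 adjusted over the list alone), including the complex I subunit genes Ndufs3 (-0.57) and Ndufs4 (-0.44). The camera adjusted p was 9.42e-06, and the adjusted p = 0.264 with an estimated correlation. Of the 23 genes of glycolysis and glucose transport, 5 rose and 5 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.686), with rises of Slc16a1 (1.39), a lactate transporter, and Slc2a3 (1.01), the neuronal glucose transporter.

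Smaller shifts were seen in control mice for antioxidant, clock and glutamate receptor genes. Of the 18 NRF2 and antioxidant genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone), including Hmox1 (1.51), heme oxygenase 1, and Srxn1 (1.09), sulfiredoxin, with a camera adjusted p of 0.0441 and an adjusted p = 0.355 with an estimated correlation. Of the 18 circadian clock genes, 7 rose and 2 fell (8 and 4 adjusted over the list alone); Nfil3 (2.00) and Per1 (1.37), repressors within the clock, rose, and Dbp (-1.18) and Tef (-0.60), its PAR bZIP activators, fell. The circadian list had a camera adjusted p of 0.0441 and an adjusted p = 0.422 with an estimated correlation. Of the 20 glutamate receptors, 0 rose and 4 fell (0 and 6 adjusted over the list alone), among them Grm2 (-1.01), a metabotropic receptor, and Grin3a (-0.38), an NMDA receptor subunit, with a camera adjusted p of 0.0114 and an adjusted p = 0.211 with an estimated correlation. Leaving out 1 array ended the NRF2 call for control saline replicates 3 and 4, control SE replicates 1 and 2 and the array labelled control SE replicate 4 (adjusted p from 0.0593 to 0.0904), the circadian call for control saline replicate 1, control SE replicate 2 and Astro-D2KO saline replicate 3 (0.0645 to 0.140), and the glutamate receptor call for the array labelled control SE replicate 4 (0.0593). Tef did not pass without control saline replicate 3 (-0.51), control saline replicate 4 (-0.49) or the array labelled control SE replicate 4 (-0.48), or as the mean of its probe sets (-0.33), and Grin3a did not pass without control saline replicate 2 (-0.31) or control SE replicate 1 (-0.32).

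Thyroid hormone genes moved singly in control mice, and camera called none of their 3 lists, while fry called the genes lowered by T3 (adjusted p = 0.00444). Of the 20 genes of thyroid hormone metabolism, transport and receptors, 2 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.534). Slco1a4 had the largest fall of them, and Thra, the main thyroid hormone receptor gene of brain, dropped by 0.32 ± 0.084 (adjusted p = 0.0106). Of the 25 genes raised by T3 in brain, 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.941); Klf9, a transcription factor induced by T3 and by glucocorticoids, rose by 0.35 ± 0.093 (adjusted p = 0.0115), and Dbp fell. Of the 12 genes lowered by T3, 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.303), the rises being of Aldh1a3 (1.37), a retinoic acid synthesising enzyme, and Scg2 (1.69), a granin of secretory vesicles. Scg2 is also on the list of later activity-regulated genes, and Dio2 is on that of genes lowered by T3. No fry result without these members is given here. The receptor gene Thrb (-0.18), Hr (0.09), a corepressor induced by T3, and Dio3 (0.00), the deiodinase that inactivates T3, did not pass.

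The lists of GABA signalling, voltage-gated channels and interneurons were not called by camera in control mice, and fry called the voltage-gated channels (adjusted p = 0.0334). Of the 19 GABA signalling genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.594), with rises of Gabra2 (0.76), a GABA-A receptor subunit, and Gad1 (0.73), a GABA synthesising enzyme. Of the 31 voltage-gated channels, 2 rose and 8 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.194), including a rise of Kcnf1 (0.84), a potassium channel subunit, and a fall of Cacna1h (-1.03), a T-type calcium channel. Of the 17 interneuron markers, 2 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.384), the rises being of Gad1 and Sst (0.57), somatostatin.

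No cell type marker list was called by camera in control mice, while fry called those of astrocytes, microglia, pericytes and blood cells (adjusted p from 0.00189 to 0.0344). Of the 18 astrocyte markers, 1 rose, Sox9 (0.58), and 4 fell, including Fgfr3 (-0.87), with 1 and 5 adjusted over the list alone and a camera adjusted p of 0.0717. Of the 16 microglia markers, 0 rose and 5 fell (0 and 5 adjusted over the list alone; camera adjusted p = 0.0748), among them P2ry12 (-1.02), a purinergic receptor of resting microglia, and Selplg (-0.83). Oligodendrocyte markers (12 measured) had 0 rises and 0 falls and their precursor markers (9 measured) 0 rises and 3 falls, as they did adjusted over the list alone, with camera adjusted p of 0.572 and 0.205. For the 15 endothelial markers, 4 rose, Cdh5 (1.41) and the glucose transporter gene Slc2a1 (0.66) among them, and 3 fell, Slco1a4 the most (4 and 4 adjusted over the list alone; camera adjusted p = 0.530). Pericyte and smooth muscle markers (11 measured) had 1 rise and 3 falls, counts that were 1 and 3 adjusted over the list alone, with a camera adjusted p of 0.288. Choroid plexus markers (12 measured) had 0 and 0 (0 and 0 adjusted over the list alone; camera adjusted p = 0.915), leptomeningeal fibroblast markers (10 measured) 0 and 1 (0 and 0 adjusted over the list alone; 0.530) and blood cell markers (7 measured) 2 and 0 (2 and 0 adjusted over the list alone; 0.0937). Without control saline replicate 1, control SE replicate 1 or control SE replicate 2 the astrocyte list was called (adjusted p from 0.0205 to 0.0441), and without control saline replicate 3, control saline replicate 4 or control SE replicate 1 the microglia list was called (0.0311 to 0.0437).

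Neuronal and regional marker lists were not called by camera in control mice, while fry called the pan-neuronal (adjusted p = 0.00246) and striatum lists (0.00113). Among 13 pan-neuronal markers 1 rose, the neurofilament gene Nefl (0.86), and 2 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.223). Dentate granule cell markers (13 measured) had 1 rise and 5 falls, Dsp and Lct the largest (1 and 6 adjusted over the list alone; 0.251). CA1 pyramidal cell markers (8 measured) had 0 and 0 (0 and 0 adjusted over the list alone; 0.463), and CA2 and CA3 pyramidal cell markers (13 measured) had 1 and 1 (1 and 1 adjusted over the list alone; 0.953). Thalamus and habenula markers (13 measured) had 2 rises and 0 falls (2 and 0 adjusted over the list alone; 0.381), striatum markers (9 measured) 4 and 1 (4 and 1 adjusted over the list alone; 0.0581) and neocortex markers (12 measured) 2 and 0 (2 and 0 adjusted over the list alone; 0.0748). The largest rises of the striatum list were of the neuropeptide precursor genes Tac1 (1.56) and Penk (1.26), which are also on the list of later activity-regulated genes. Sex-linked genes (4 measured) had 1 rise and 1 fall (1 and 1 adjusted over the list alone; 0.734). The striatum list was called without control saline replicate 1, control SE replicate 1 or control SE replicate 3 (adjusted p from 0.0327 to 0.0416), and the neocortex list without control SE replicate 1 or the array labelled control SE replicate 4 (0.0272 to 0.0315). The median, mean and test differed in sign for 5 of the 38 lists, none of them called: genes raised by T3, glycolysis, oligodendrocytes, endothelium, and CA2 and CA3.

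**Figure D2:**
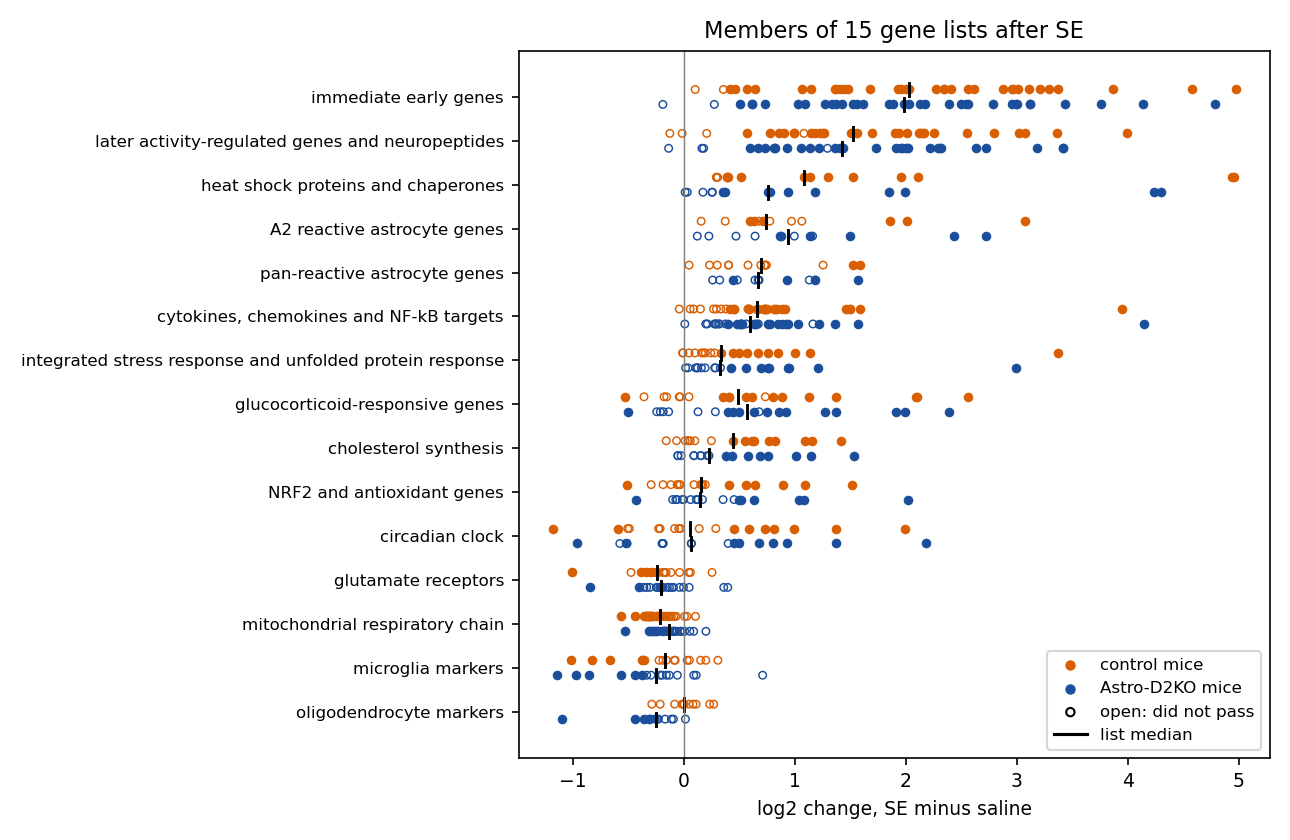
Log2 change, SE minus saline (horizontal axis), of each measured member of 15 gene lists, for control mice and Astro-D2KO mice. Each point is a gene, filled if it passed an adjusted p of 0.05, and black bars are list medians, such as 2.03 for immediate early genes in control mice. The arrays labelled control SE replicate 4 and Astro-D2KO SE replicate 1 are in their labelled groups.

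The second comparison asked the same of Astro-D2KO mice. Npas4 again rose the most, by 4.78 ± 0.39 (27.6-fold, n = 4 against 4), followed by Hspa1a (4.30 ± 0.32), Hspa1b (4.23), Ccl3 (4.15 ± 0.41) and Fosb (4.13 ± 0.17). Fos (3.76), Nr4a2 (3.43), an activity-induced nuclear receptor, Pcsk1 (3.42), Gadd45g (3.41), a stress-induced growth arrest gene, and Lilrb4a (3.35, and 3.95 without Astro-D2KO saline replicate 4), an inhibitory receptor of myeloid cells, were the others of the 10 largest rises. Slco1a4 dropped by 2.01 ± 0.21 to a level 4.02-fold lower than under saline. Further falls were of the zinc finger genes Zkscan16 (-1.58) and Zfp932 (-1.12), of P2ry12 (-1.14), of Aspa (-1.10), the aspartoacylase of oligodendrocytes, and of Vmn2r85 (-1.32), AB010352 (-1.22), Fam163b (-1.22), Ppil6 (-1.19) and Syna (-1.15).

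In Astro-D2KO mice limma called 4459 genes, 1661 of which rose and 2798 fell (1849 and 2358 with median centring, 1755 and 2519 with quantile normalisation repeated), with at least a 2-fold change in 274 and 39 of them. The group included the array labelled Astro-D2KO SE replicate 1, whose Dio2 level went against its label. Immediate early genes had 33 rises of 35 and 0 falls (34 and 0 adjusted over the list alone; camera adjusted p = 9.34e-47) and later activity-regulated genes 28 of 33 and 0 (29 and 0 adjusted over the list alone; 1.09e-31). Both calls held with an estimated correlation (adjusted p = 0.00402 for each). The other 12 of 14 list calls were lost with it. Heat shock proteins and chaperones had 10 rises of 15 and 0 falls (11 and 0 adjusted over the list alone; camera adjusted p = 1.67e-10, and adjusted p = 0.0535 with an estimated correlation).

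Cytokines, chemokines and NF-kB targets in Astro-D2KO mice had 19 rises of 32 and 0 falls (24 and 0 adjusted over the list alone; camera adjusted p = 5.12e-14, and adjusted p = 0.0621 with an estimated correlation). Pan-reactive astrocyte genes had 4 rises of 13 (7 adjusted over the list alone; 0.000296, and adjusted p = 0.380 with an estimated correlation) and A2 genes 6 of 12 (8 adjusted over the list alone; 2.72e-07, and adjusted p = 0.186 with an estimated correlation), with 0 falls in each. Glucocorticoid-responsive genes had 12 rises and 1 fall of 20 (13 and 1 adjusted over the list alone; 6.58e-08, and adjusted p = 0.0621 with an estimated correlation), and stress response genes 9 and 0 of 19 (12 and 0 adjusted over the list alone; 5.56e-09, and adjusted p = 0.0902 with an estimated correlation). Cholesterol synthesis genes had 8 rises and 0 falls of 17 (8 and 0 adjusted over the list alone; 7.27e-08, and adjusted p = 0.0902 with an estimated correlation), and NRF2 and antioxidant genes 6 and 1 of 18 (7 and 1 adjusted over the list alone; 0.00438, and adjusted p = 0.188 with an estimated correlation). Striatum markers had 4 rises and 0 falls of 9, with Tac1 and Penk the largest (5 and 1 adjusted over the list alone; 0.00530, and adjusted p = 0.0621 with an estimated correlation).

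The 3 lists called as lower by camera after SE in Astro-D2KO mice were those of the respiratory chain, microglia and oligodendrocytes. Respiratory chain genes had 7 falls of 32 and 0 rises (7 and 0 adjusted over the list alone; camera adjusted p = 0.00438, and adjusted p = 0.441 with an estimated correlation). Microglia markers had 6 falls of 16, P2ry12 the largest, and 0 rises (7 and 0 adjusted over the list alone; 0.00348, and adjusted p = 0.316 with an estimated correlation). Oligodendrocyte markers had 4 falls of 12, with Aspa the largest and Mbp and Ugt8a among them, and 0 rises (5 and 0 adjusted over the list alone; 0.00987, and adjusted p = 0.441 with an estimated correlation). Without Astro-D2KO SE replicate 2 the oligodendrocyte adjusted p was 0.0911, which ended that call. Of the 16 fits without 1 array, camera also called the voltage-gated channels in 6 (adjusted p from 0.0374 to 0.0454). It called the circadian clock in 6 (0.0178 to 0.0491) and the glutamate receptors in 2 (0.0423 and 0.0486). The median, mean and test differed in sign for 9 of the 38 lists, none of them called.

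The responses of the 2 genotypes to SE were close to each other. Of the genes called, 1259 rose and 2008 fell in both genotypes, 3267 in all, against 140 and 383 for independent lists, and 3 were called in opposite directions. Across genes, which are not independent replicates, the 2 sets of log2 changes had a Pearson correlation of 0.867 and a Spearman correlation of 0.718. Of the genes called in control mice alone (1637) or Astro-D2KO mice alone (1189), 92.4% and 92.1% had the same sign in the other genotype. The comparisons share no array. They do share the spread per gene of the same fit, so the numbers for independent lists are not an exact expectation. Averaged over genotypes, limma called 7233 genes, of which 2675 rose, led by Npas4 (4.88) and Hspa1a (4.62), and 4558 fell, led by Slco1a4 (-2.08). With median centring 3212 rose and 3960 fell, and with quantile normalisation repeated 2842 and 4202. In that average 14 lists were called, 11 up and 3 down, and 3 held with an estimated correlation (smallest adjusted p = 0.00537): immediate early genes, later activity-regulated genes, and heat shock proteins and chaperones.

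**Figure D3:**
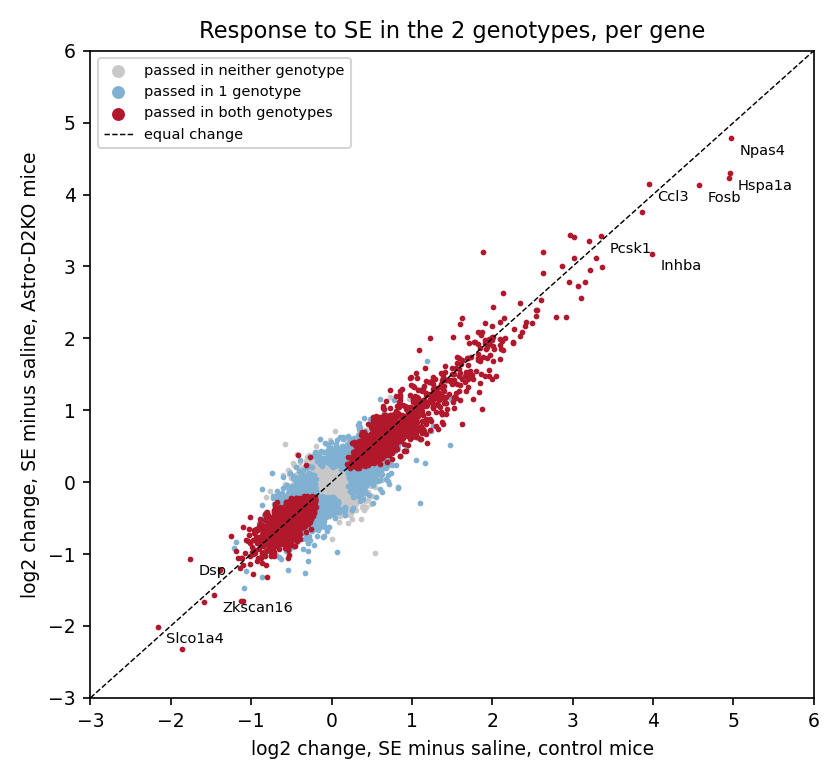
Log2 change after SE in control mice (horizontal axis) and in Astro-D2KO mice (vertical axis), with 1 point per gene, coloured by how many genotypes it passed the test in. The dashed line marks equal change, and the Pearson correlation across genes was 0.867. Npas4 and Hspa1a lie at the upper end and Slco1a4 at the lower end in both genotypes. The arrays labelled control SE replicate 4 and Astro-D2KO SE replicate 1 are in their labelled groups.

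The third comparison asked what the loss of astrocyte Dio2 does without seizures. Dio2 itself differed by -1.36 ± 0.35 between Astro-D2KO and control mice under saline (n = 4 each, 2.57-fold lower, exact permutation p = 0.0286), and its limma adjusted p was 0.999. The limma value uses the spread of all 4 groups, a residual SD of 0.582, to which the SE arrays contribute. Mpc1, a subunit of the mitochondrial pyruvate carrier, stood at -0.46 ± 0.083 with the smallest adjusted p, 0.804. A second, dimmer Mpc1 probe set with a mean of 7.39 stood at -0.14. Myom1 (-0.37), Vsig8 (0.39) and Clec4b2 (0.43) had the next smallest raw p among the genes the naming rule admits, and none of them passed. Klf9, the T3-induced transcription factor, differed by -0.24 ± 0.093 (adjusted p = 0.999).

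Limma called 0 of the 22180 genes under saline, with 885 at an unadjusted p under 0.05 against 1109 expected by chance, and no other gene-level tool was run. Dio2 was the 1 gene called in the fit of only the 2 saline groups (adjusted p = 0.0150) and without the pair of doubted SE arrays (0.000271); its adjusted p ran from 0.000271 to 1.00 over the alternatives. Camera called 9 of the 38 lists, all of which were lost with an estimated correlation, and 0 were called by fry. Lower as lists were those of pericytes and smooth muscle (camera adjusted p = 0.00302; adjusted p = 0.421 with an estimated correlation), with the myosin light chain gene Myl9 at -0.27, and of glucocorticoid-responsive genes (0.0120; adjusted p = 0.681 with an estimated correlation), with the stress gene Ddit4 at -0.45. So were leptomeningeal fibroblast markers (0.0177; adjusted p = 0.793 with an estimated correlation), with the transporter gene Slc6a13 at -0.32, and thyroid hormone metabolism, transport and receptors (0.0227; adjusted p = 0.592 with an estimated correlation), in which Dio2 was 1 of 17 negative members. Astrocyte markers (0.0270; adjusted p = 0.793 with an estimated correlation) included the connexin gene Gjb6 at -0.37, and oligodendrocyte precursor markers (0.0270; adjusted p = 0.681 with an estimated correlation) Olig1 at -0.33. Circadian clock genes were lower too (0.0362; adjusted p = 0.681 with an estimated correlation). Higher were later activity-regulated genes (0.00425; adjusted p = 0.681 with an estimated correlation), with Inhba at 0.80, and blood cell markers (0.0456; adjusted p = 0.421 with an estimated correlation). No member of these 9 lists passed over all genes, and adjusted over the list alone 1 did, Dio2 in the thyroid hormone list. Dio2 is the targeted gene, and no result for that list without Dio2 is given here. The number of lists called was 3 without control saline replicate 2, 4 without control saline replicate 4, 3 without Astro-D2KO saline replicate 1, 2 without Astro-D2KO saline replicate 4 and 15 without Astro-D2KO saline replicate 3. The blood cell call ended in 9 of the 16 fits without 1 array (adjusted p from 0.0504 to 0.157; control saline replicates 1, 2 and 3, control SE replicates 1 and 2, Astro-D2KO saline replicates 2, 3 and 4, and Astro-D2KO SE replicate 3). The thyroid hormone (0.0501 to 0.153) and clock calls (0.0706 to 0.334) each ended in 6, for control saline replicates 2, 3 and 4 and Astro-D2KO saline replicates 1, 2 and 4. The astrocyte (0.0884 to 0.246) and oligodendrocyte precursor calls (0.0727 to 0.200) each ended for control saline replicates 2 and 4 and Astro-D2KO saline replicates 1 and 4. The leptomeningeal call (0.0726 to 0.246) ended for control saline replicates 2 and 3 and Astro-D2KO saline replicates 1 and 4. The glucocorticoid call (0.0559 to 0.220) ended for control saline replicates 1 and 4 and Astro-D2KO saline replicates 1 and 3. That of later activity-regulated genes (0.0741 to 0.246) ended for control saline replicates 3 and 4 and Astro-D2KO saline replicate 4.

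The fourth comparison asked how the genotypes differ after SE. No gene passed, and the oligodendrocyte marker list, called as lower in Astro-D2KO mice by camera, was not called with an estimated correlation (adjusted p = 0.101). All 12 oligodendrocyte markers had negative differences, from -0.72 to -0.26 with a median of -0.38, among them Mbp, myelin basic protein (-0.38 ± 0.095), and Ugt8a, which makes the myelin lipid galactocerebroside (-0.46 ± 0.11). The array mean of the list was 0.13 ± 0.19 in control mice and -0.27 ± 0.19 in Astro-D2KO mice (SD, n = 4 each; difference -0.40, exact permutation p = 0.0571), with the array labelled control SE replicate 4 at -0.14. Among the 5 genes with the smallest raw p that the naming rule admits were Enpp6 (-0.63 ± 0.12), a phosphodiesterase of newly formed oligodendrocytes, and Fa2h (-0.50 ± 0.10), which makes hydroxylated myelin lipids, both with an adjusted p of 0.532.

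Limma called 0 of the 22180 genes between the genotypes after SE, with 1358 at an unadjusted p under 0.05, a smallest adjusted p of 0.0753, and no other gene-level tool run. Dio2 differed by -1.41 ± 0.35 (adjusted p = 0.532; from 1.35e-06 to 1.00 over the alternatives). Sh3gl3 (-0.40, adjusted p = 0.397), Tmco5 (-0.79) and Fbxo32 (-0.44), a ubiquitin ligase subunit, completed the 5 named genes, and Klf9 differed by -0.15. Camera called 4 lists, all lower in Astro-D2KO mice and all lost with an estimated correlation. Oligodendrocyte markers had a camera adjusted p of 3.24e-16 with 0 members past the threshold over all genes (11 falls adjusted over the list alone) and an adjusted p = 0.101 with an estimated correlation; fry gave 0.0431 and called no other list. Genes raised by T3, with Mbp among them, had 0 (1 fall adjusted over the list alone; 0.00134, and adjusted p = 0.722 with an estimated correlation). Heat shock proteins and chaperones, with the small heat shock protein gene Cryab at -0.43, had 0 (1 fall adjusted over the list alone; 0.00269, and adjusted p = 0.722 with an estimated correlation), and thalamus and habenula markers, with the calretinin gene Calb2 at -0.79, had 0 (0 adjusted over the list alone; 0.0295, and adjusted p = 0.722 with an estimated correlation). These directions rest on groups that hold the doubted arrays: without the array labelled control SE replicate 4, Fa2h (-0.60) and Serpinb2 (2.27), an inhibitor of plasminogen activators, were called with 13 lists, and without the array labelled Astro-D2KO SE replicate 1, Dio2 was called (-1.86, adjusted p = 0.0262). Without both, 5 genes were called, namely Dio2 (-2.18), Serpinb2 (2.70), the replication clamp gene Pcna (-1.03), Cip2a (-1.47) and Fa2h (-0.64), with 11 lists; Serpinb2, Pcna and Cip2a were named after their values were seen. Leaving out 1 array also ended the call of the T3 list for control SE replicate 2 (0.0804) and of the heat shock list for control SE replicate 1 and Astro-D2KO SE replicate 4 (0.108 and 0.161). It ended that of the thalamus list for control SE replicate 3 and Astro-D2KO SE replicate 2 (0.137 and 0.146), and 8 lists were called without Astro-D2KO SE replicate 3.

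**Figure D4:**
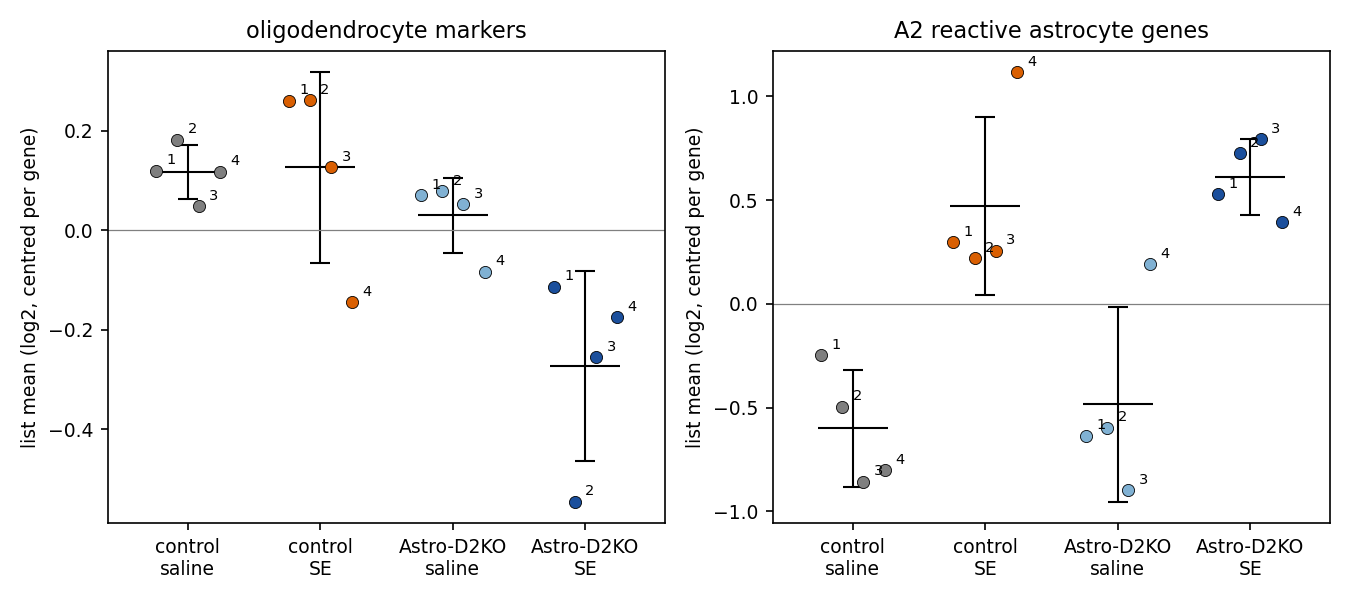
Mean of the oligodendrocyte marker list and of the A2 reactive astrocyte list in each array (log2, centred per gene, vertical axes), for the 4 groups. Points are arrays numbered by replicate, and lines are the group mean and SD. The oligodendrocyte mean lies between -0.55 and -0.11 in the 4 Astro-D2KO SE arrays, and the A2 mean reaches 1.12 in the array labelled control SE replicate 4.

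Averaged over treatments, Dio2 stood lower in Astro-D2KO mice by a log2 difference of -1.39 ± 0.25 (n = 8 arrays against 8; limma adjusted p = 0.612). Cnr1, the cannabinoid receptor gene of interneurons (0.23), Orm3, an acute phase protein gene (0.52), Fbxo32 (-0.32) and Cyp2b23 (-0.34) had the next smallest raw p among the genes the naming rule admits, and Mal, a myelin protein gene, stood at -0.22 and Klf9 at -0.19. None passed: limma called 0 genes, with 1191 at an unadjusted p under 0.05 and no other gene-level tool run. Without the array labelled Astro-D2KO SE replicate 1, Dio2 alone was called (-1.61), and without both doubted arrays Dio2 (-1.77) and Serpinb2 (1.34) were. Camera called 11 lists, 10 lower and 1 higher, and 0 were called with an estimated correlation or by fry. Oligodendrocyte markers had all 12 members negative with a median of -0.25 (0 passed over all genes, 11 adjusted over the list alone; camera adjusted p = 1.95e-13, and adjusted p = 0.188 with an estimated correlation). Genes raised by T3 and glucocorticoid-responsive genes had 20 of 25 and 16 of 20 members negative (0.00129 for each, and adjusted p = 0.355 with an estimated correlation for each; 0 and 1 passed adjusted over the list alone). The other lower lists were those of the clock, pericytes, oligodendrocyte precursors, astrocytes, leptomeningeal fibroblasts, thalamus and habenula, and thyroid hormone metabolism, and the higher list was that of later activity-regulated genes, with camera adjusted p from 0.00187 to 0.0482 and adjusted p from 0.355 to 0.703 with an estimated correlation. The thyroid hormone list holds Dio2, the targeted gene, and here too no result without Dio2 is given. The number of lists called was 7 without control saline replicate 2, 5 without control saline replicate 4, 7 without control SE replicate 3, 7 without Astro-D2KO saline replicate 1, 7 without Astro-D2KO saline replicate 4 and 6 without Astro-D2KO SE replicate 2. Of the 16 fits without 1 array, the thyroid hormone call ended in 10 (adjusted p from 0.0545 to 0.195; control saline replicates 2, 3 and 4, control SE replicates 1, 2 and 3, Astro-D2KO saline replicates 1, 2 and 4, and Astro-D2KO SE replicate 2). The astrocyte call ended in 9 (0.0613 to 0.215; control saline replicates 2 and 4, control SE replicates 1, 2 and 3, Astro-D2KO saline replicates 1 and 4, and Astro-D2KO SE replicates 2 and 3). The leptomeningeal call ended in 9 (0.0577 to 0.237; control saline replicates 2, 3 and 4, control SE replicate 1, the array labelled control SE replicate 4, Astro-D2KO saline replicates 1 and 4, the array labelled Astro-D2KO SE replicate 1, and Astro-D2KO SE replicate 2). The thalamus call ended in 7 (0.0511 to 0.127; control saline replicates 2 and 4, control SE replicate 3, the array labelled control SE replicate 4, Astro-D2KO saline replicates 1 and 4, and Astro-D2KO SE replicate 2). The oligodendrocyte precursor call ended in 4 (0.0545 to 0.0795; control saline replicate 4, control SE replicate 3, Astro-D2KO saline replicate 4 and Astro-D2KO SE replicate 2). That of later activity-regulated genes ended in 2 (0.0707 and 0.127; control saline replicate 4 and Astro-D2KO saline replicate 4).

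The interaction asked whether the response to SE depends on the genotype. No gene passed, and the smallest adjusted p was 0.971. Among the genes the naming rule admits, the 5 with the smallest raw p were Pate7 (0.50 ± 0.12), Tagap1 (-0.81 ± 0.19), Zfp992 (0.87 ± 0.21), Gucy2c, a guanylate cyclase receptor (-0.91 ± 0.22), and Mpc1 (0.47 ± 0.12), each with an adjusted p of 0.998 (4 arrays in each of 4 groups). The Mpc1 probe set used changed with SE by -0.18 in control and 0.29 in Astro-D2KO mice. The dimmer Mpc1 probe set changed by 0.03 and 0.05, so it did not show this difference. Oligodendrocyte markers had the smallest list p, with all 12 members negative, a median of -0.28 and the myelin gene Ermn at -0.36 (camera adjusted p = 2.51e-06, and adjusted p = 0.721 with an estimated correlation). Heat shock proteins and chaperones had lower log2 changes in Astro-D2KO mice as a list, with 14 of 15 members negative, a median of -0.26 and the chaperone gene Hsph1 at -0.52 (0.000729, and adjusted p = 0.721 with an estimated correlation). Respiratory chain genes had 26 of 32 members positive, a median of 0.080 and Ndufs3 at 0.29 (0.0337, and adjusted p = 0.834 with an estimated correlation). In none of these 3 lists did a member pass, either over all genes or adjusted over the list alone. Limma called 0 of the 22180 genes, with 1031 at an unadjusted p under 0.05, and no other gene-level tool was run; without both doubted arrays 1 gene was called, Serpinb2 (2.72). The respiratory chain call ended in 9 of the 16 fits that left out 1 array (adjusted p from 0.0550 to 0.296; control saline replicates 1 and 2, control SE replicates 1 and 3, Astro-D2KO saline replicates 1 and 2, the array labelled Astro-D2KO SE replicate 1, and Astro-D2KO SE replicates 2 and 4). The number of lists called was 5 without control saline replicate 1, 5 without the array labelled control SE replicate 4 and 7 without Astro-D2KO saline replicate 3.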

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

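The 2 tests of reactive astrocyte scores, the exact test of the oligodendrocyte list mean and the choroid plexus test were chosen only after the result was seen; the genotype score, the second oligodendrocyte set and the counts over splits of the arrays were fixed before theirs.

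Dio2 stood at 8.91 in the array labelled Astro-D2KO SE replicate 1, against 7.03 to 7.17 in the other Astro-D2KO SE arrays, and its gap made up 0.925 of the range of that group. In the array labelled control SE replicate 4 it stood at 7.99, against 9.11 to 9.51 in the other control SE arrays. An exchange of these 2 labels cannot be told apart from their being right: a score made of the 100 genes that differed most between the saline groups did not separate the other 6 SE arrays (-0.034 to 0.008 in control, -0.009 to 0.025 in Astro-D2KO mice) and differed by -0.0127 between the 2 arrays. A stronger reactive response in the control array, or a weaker one in the Astro-D2KO array, was not decided by the A2 list means: 0 of the other 7 SE arrays lay above the control array, a value seen before that test was chosen, and 1 of the other 3 Astro-D2KO SE arrays lay below the Astro-D2KO array, which was within their spread. A mislabelled or mixed sample, incomplete deletion of Dio2 and a biological difference between mice, the reactive response included, all stay open.

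Oligodendrocyte markers were lower in Astro-D2KO than in control mice after SE, with a list mean differing by -0.40. Less oligodendrocyte tissue in the Astro-D2KO pieces may account for it: 25 of 26 genes of a second oligodendrocyte set, which shares no gene with any list, were lower too (median -0.23, from -0.46 to 0.09; camera p = 9.24e-15 with the preset correlation and p = 0.00713 with an estimated correlation). That set does not separate fewer cells or another dissection from lower expression in each cell. Variation between arrays unrelated to genotype stays open as well, since the exact permutation p of the list mean was 0.0571 and the array labelled control SE replicate 4 (-0.14) lay among the Astro-D2KO SE arrays (-0.55 to -0.11). An effect of the genotype stays open and was tested only by these comparisons.

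Choroid plexus markers were uneven within groups: Ttr, the thyroxine carrier made by choroid plexus, ran from 7.90 to 13.09 in control saline, 9.08 to 12.74 in control SE, 8.84 to 12.66 in Astro-D2KO saline and 7.45 to 13.03 in Astro-D2KO SE arrays. The other 11 measured markers of the list were highest in the array where Ttr was highest in 44 of 44 marker and group pairs, against 11 expected by chance, which is consistent with choroid plexus tissue carried in with some pieces. The gap of the list mean made up 0.842 of the range in Astro-D2KO saline (replicate 3) and 0.835 in Astro-D2KO SE (replicate 4). No biological explanation was tested.

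A test of the difference between the genotypes' SE responses gave 3 lists: heat shock proteins and chaperones with a median of -0.26, oligodendrocyte markers with -0.28 and the mitochondrial respiratory chain with 0.080. These 3 were called with the preset correlation, and 0 lists were called with an estimated correlation or by fry.

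Arrays that stood apart from the other 3 of their group were sought by the share of the group's range taken up by the gap. Chance puts about 1 in 20 groups of 4 arrays above Dixon's 95% critical value. Among 384 groups of values for the named genes 25 lay above it, against 19.2 expected, and among 152 groups of list means 12 did, against 7.6 expected. The array labelled control SE replicate 4 had 6 of them, Astro-D2KO saline replicate 4 had 5 and control SE replicate 2 had 4.

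In control saline arrays the shares were 0.8293 for Dbp and 0.942 for Mpc1 (replicate 1), 0.924 for Hspa1b (replicate 3) and 0.884 for Zfp932 (replicate 4). In control SE arrays they were 0.941 for Calb2, 0.870 for Cnr1, 0.934 for Gabra2 and 0.860 for Zfp992 (replicate 2), 0.922 for Slco1a4 and 0.936 for Zfp932 (replicate 3), and, in the array labelled replicate 4, 0.831 for Fa2h, 0.919 for Fosb and 0.8294 for Npas4. In Astro-D2KO saline arrays they were 0.866 for Zfp975 (replicate 1), 0.840 for Slc6a13 (replicate 2), 0.833 for Tef and 0.843 for Zfp932 (replicate 3), and 0.863 for Ccl3, 0.890 for Egr1, 0.962 for Olig1 and 0.915 for Slc16a1 (replicate 4). In Astro-D2KO SE arrays they were 0.876 for Clec4b2 in the array labelled replicate 1, 0.857 for Vmn2r85 (replicate 3) and 0.830 for Egr1 (replicate 4).

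Among list means in control arrays the shares were 0.843 for glycolysis and glucose transport (saline replicate 1), 0.881 for thyroid hormone metabolism, transport and receptors (SE replicate 1) and, in the array labelled control SE replicate 4, 0.916 for A2 reactive astrocyte genes, 0.841 for glucocorticoid-responsive genes and 0.952 for oligodendrocyte precursor markers. In Astro-D2KO arrays they were 0.870 for neocortex markers (saline replicate 1), 0.840 for oligodendrocyte markers (saline replicate 4), 0.891 for CA1 pyramidal cell markers (the array labelled SE replicate 1), 0.858 for A1 reactive astrocyte genes (SE replicate 3) and 0.952 for thalamus and habenula markers (SE replicate 4). The thyroid hormone list holds Ttr, which among control SE arrays was also highest in replicate 1 (12.74). How much of the gap of that list Ttr makes up was not tested.

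Probe sets outside the gene comparisons also changed with SE, averaged over genotypes. Of 16010 probe sets without a listed gene 1923 passed the threshold, and of 1814 with several symbols 431 did. The largest changes of probe sets without a listed gene were a rise of 3.83 and a fall of -2.04.

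Splits of the same arrays into groups of the same sizes were counted for each comparison. For SE in control mice, 1 of the 35 splits gave as many genes, the real one (4907, highest other 1), for SE in Astro-D2KO mice 1 of the 35 (4459, highest other 0), and for SE averaged over genotypes 1 of the 100 drawn (7233, highest other 3289). In these 3 the real split thus gave more genes than any other. That is the smallest share that 35 or 100 splits can give, so the counts exclude chance no further than that. A batch that went with treatment could give the same counts, and any hybridisation batch is not given. For the knockout comparisons limma called 0 genes, so every split gives as many by construction and these counts decide nothing about chance: 35 of the 35 splits under saline (highest other 42; 885 genes at an unadjusted p under 0.05), 35 of the 35 after SE (highest other 150; 1358), 100 of the 100 averaged over treatments (highest other 9; 1191) and 100 of the 100 for the interaction (highest other 5; 1031). The split after SE with 150 genes exchanged the array labelled control SE replicate 4 with Astro-D2KO SE replicate 4, its exchange with the array labelled Astro-D2KO SE replicate 1 gave 75, and its exchange with Astro-D2KO SE replicate 2 or 3 gave 0 for each. These splits point to a structure among the arrays that sets the array labelled control SE replicate 4 with Astro-D2KO SE replicates 2 and 3: on the second principal component these 3 stood at 19.47, 10.31 and 10.30, and the other 5 SE arrays from -16.34 to -3.58. That component divided the saline arrays too. Replicates 1 to 4 stood at 12.28, 5.16, -12.62 and -14.62 in control saline and at 8.31, 5.045, -11.64 and 14.36 in Astro-D2KO saline. The structure is thus not confined to the SE arrays.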

How the results depend on the processing

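Leaving out the arrays labelled control SE replicate 4 and Astro-D2KO SE replicate 1 together, the fits without each of the 16 such pairs and the covariate fits were chosen only after the result was seen; the other alternatives were fixed before the data were examined. At an adjusted p under 0.01 the genes changed by SE numbered 2926 in control mice and 2548 in Astro-D2KO mice, and with a 1.5-fold minimum 1260, 1209 and, averaged over genotypes, 1183, as stricter thresholds require. With the replicate block, since the numbers do not pair the mice (4 of 24 same-number pairs correlated above 0.1), the 3 SE counts were 4576, 4109 and 6967 and the 4 knockout counts 0 each; the circadian list in control mice (adjusted p = 0.0510) and the blood list under saline (0.0559) lost their calls, and the circadian list gained one for the knockout after SE (0.0402, from 0.0508). Without 1 array the SE counts ran from 3998 to 4971 in control mice, 3486 to 4707 in Astro-D2KO mice and 6646 to 7286 averaged.

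Limma called 0 genes for the knockout in most alternatives. Without 1 array the counts ran from 0 to 2 after SE (2 without the array labelled control SE replicate 4, 1 without the array labelled Astro-D2KO SE replicate 1), from 0 to 1 averaged over treatments (1 without the latter) and stayed at 0 under saline and for the interaction. Without both they were 1 under saline, 5 after SE, 2 averaged and 1 for the interaction; of the 16 pairs left out, only this pair gave any gene after SE, 4 besides Dio2, while the array labelled control SE replicate 4 with Astro-D2KO SE replicate 4 gave 2528 genes at an unadjusted p under 0.05 against 2508 for this pair. With only the 2 saline groups in the fit the count was 1, Dio2. The Dio2 difference under saline was -1.36 in each of these fits, so its calls there came from the smaller spread of the arrays left in the fit; the cause was not tested for the calls of other genes.

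The 2 arrays were doubted for their Dio2 levels, so the Dio2 values without either or both are no independent evidence. Leaving out both gave Dio2 differences of 1.14 for SE in control mice, -1.36 for the knockout under saline and -2.18 after SE, all past the threshold, as was -1.36 in the fit of the 2 saline groups and 0.82 for SE in control mice with the first principal component as a covariate (adjusted p = 0.0458, range over alternatives 2.69e-05 to 0.504). The dimmer Dio2 probe set reversed the SE differences, -0.33 in control and -0.36 in Astro-D2KO mice; the cause was not tested. Without 1 array the SE difference in control mice ran from 0.64 to 1.14, past the threshold without the array labelled control SE replicate 4 (1.14) or Astro-D2KO SE replicate 1 (0.82), and that in Astro-D2KO mice from 0.32 (without the array labelled replicate 1) to 0.95. The knockout difference ran from -1.46 to -1.27 under saline and from -1.86 (without the array labelled Astro-D2KO SE replicate 1, past the threshold) to -1.23 after SE. The correlation of the 2 SE responses was 0.911 without the genes of lowest mean level, 0.721 over every probe set and 0.824 without both doubted arrays; the cause was not tested.

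Called lists fell with an estimated correlation from 13 to 3 for SE in control mice, 14 to 2 in Astro-D2KO mice, 14 to 3 averaged, and 9, 4, 11 and 3 to 0 for the knockout under saline, after SE, averaged and the interaction. Fry gave 21 for SE in control mice, 20 in Astro-D2KO mice, 27 averaged, and 0, 1, 0 and 0 for the knockout contrasts. Without both doubted arrays 11 lists were called after SE. Without 1 array the calls ran from 2 (without Astro-D2KO saline replicate 4) to 15 (without Astro-D2KO saline replicate 3) under saline, 3 to 13 (without the array labelled control SE replicate 4) after SE, 5 (without control saline replicate 4) to 15 averaged (6 without Astro-D2KO SE replicate 2, and 7 without control saline replicate 2, control SE replicate 3 or Astro-D2KO saline replicates 1 or 4) and 2 to 7 (without Astro-D2KO saline replicate 3) for the interaction; the cause was not tested. Lists not called with all arrays gained calls too. For the knockout after SE the circadian list did in 8 of the 16 fits (adjusted p from 0.000366 to 0.0476; without control saline replicates 1 or 2, the array labelled control SE replicate 4, Astro-D2KO saline replicates 1, 3 or 4, the array labelled Astro-D2KO SE replicate 1 or Astro-D2KO SE replicate 3). Immediate early genes did in 6 (1.57e-05 to 0.0476; without control saline replicate 2, the array labelled control SE replicate 4, Astro-D2KO saline replicates 1, 3 or 4, or Astro-D2KO SE replicate 4). Neocortex markers (6 fits, 0.0163 to 0.0483) and GABA signalling (5, 0.00737 to 0.0474) did averaged over treatments, the respiratory chain under saline (4, 0.00720 to 0.0482) and immediate early genes for the interaction (4, 0.000453 to 0.0468); each other gain for the knockout came in 3 fits or fewer. Of 3186 values of the named genes under the alternatives, which leave out the Dio2 results given above and count Dio2 only averaged over treatments, 3175 kept direction and side of the threshold, 7 (of Tef and Grin3a) no longer passed, 4 (of Fa2h and Dio2) newly passed and 0 reversed. These values do not cover the fit of every probe set, the adjusted p threshold of 0.01 or the 1.5-fold minimum. A probe set not used can differ: the dimmer one of Hspb1 changed by -0.07 with SE in control mice, against 1.53 for the one used. Neither other scaling turned the median of any of the 68 called lists. For arrays, signal over background limits what dim probe sets can show, and background was not measured here.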

Other observations

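In this part the comparisons of the zinc finger genes, by shares, random sets and camera, were chosen after the result was seen. The tests of the T3 list without its shared gene were fixed before.

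More zinc finger genes fell than rose after SE. Of 398 measured genes with the names Zfp, Zkscan or Zscan, 166 fell and 28 rose averaged over genotypes, 41.7% against 20.2% of the other genes, with a median of -0.17. In control mice 112 fell and 20 rose, and in Astro-D2KO mice 107 fell and 20 rose. Zkscan16, Zfp975 and Zfp759 were among the largest falls in control mice. With each array centred on its median 150 fell and 30 rose averaged over genotypes, and with quantile normalisation repeated 152 fell and 36 rose. Among 10000 random sets of the same mean levels 0 held as many fallen genes (median 96, highest 129), but these sets take no account of correlation between the genes, and the family was looked at after some of its members were seen among the largest falls. The camera p was 1.57e-06 with the preset correlation and p = 0.0816 with an estimated correlation. Camera does not match genes on level, so only the random sets bear on a general share of falls among genes of the same level. They would go against it if the genes varied independently. Since correlation was left out of them, that explanation stays open. Cross-hybridisation between these related genes was not tested.

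The list of genes raised by T3 in brain shares 1 gene, Mbp, with the oligodendrocyte markers. Without Mbp 18 of 24 genes were negative after SE, with a median of -0.07 (camera p = 0.000493; p = 0.0519 with an estimated correlation), and 19 of 24 averaged over treatments, with a median of -0.05 (camera p = 0.000554; p = 0.0537 with an estimated correlation). Both directions rest on the arrays as labelled, including the arrays labelled control SE replicate 4 and Astro-D2KO SE replicate 1. Mbp alone thus did not make up the difference with the preset correlation, while other genes that go with oligodendrocytes were not removed. Hr and Klf9, genes induced by T3, did not pass in any knockout comparison.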
